A study of Homo sapiens with 8 samples.

How the data were processed

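The series holds 8 RNA-seq samples of human Jurkat cells, a line grown from a T cell leukaemia. Per the labels, the samples fall into 4 groups of 2: the subclones D1.1 and B2.7, each with a control hairpin (shCtrl) and with a hairpin whose name carries PTB (shPTB). Per the labels' protocols, cells were grown in RPMI medium with serum and left untreated, and libraries were made from total RNA with the Illumina TruSeq RNA kit. That kit version does not mark the strand of a transcript.

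The deposited tables give expression as FPKM, per the file headers, which is reads scaled by gene length and by the total of the library. All 3 tables hold the same 2 value columns, 1 for B2.7 shCtrl and 1 for D1.1 shCtrl. Which of the 2 labelled samples of a group a column holds, or whether it sums both, is not given in the sources used here. The shPTB groups and the single replicates were not analysed here. Per the submitters' processing notes, the aligner was Bowtie 0.12.2 and the genome builds were mm8 and mm9. Those are mouse builds, whereas the gene coordinates in the deposited table are human GRCh38: all 58676 gene identifiers are in GENCODE release 29, and 55878 of them (95.2%) have the same coordinates there. The read counter is not given in the sources used here. Coordinates below are GRCh38 as in the deposited table.

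Each deposited FPKM value multiplied by the deposited gene length came out as a whole multiple of 1 step per column, within a tolerance of 0.02 reads for 100% of values. The multiples are the reads behind each value, so a column is 1 library or the summed reads of libraries, and not a mean of libraries scaled apart. By this count B2.7 held 26414843 reads on genes and D1.1 held 22301660. Intervals on FPKM are exact 95% Poisson intervals of these reads, and intervals on ratios of the 2 lines are exact 95% binomial (Clopper-Pearson) intervals of how the reads of a gene split between the libraries. Both cover counting error only, since 1 value per line shows no spread between replicates. They treat reads as independent, which reads without molecular identifiers are not, so they can be too narrow even for counting error. Where a gene had 0 reads in a line, the fold was set against the floor of 3 reads in that library. The lower bound is the lower end of the counting interval given beside it.

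The test fixed before the data were examined was limma on log2(FPKM + 1) over all 8 libraries. It needs replicates and was replaced by a rule of size, chosen once the columns were seen. A gene was counted as higher or lower where log2(FPKM + 1) differed by at least 1, a 2-fold difference on that scale, among the 12792 genes with a mean FPKM of at least 1. Such differences understate the ratio of genes with low values, so a ratio above 2 can stand within 2-fold on that scale. With 1 value per line no difference has a replicate check, and no p-value across genes is given. A comparison of the reads of the 2 libraries compares those libraries, not the lines as such.

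The genes named in the text follow a rule fixed before the data were examined: PTBP1, PTBP2, PTBP3 and CD40LG always, the 10 largest differences each way among genes with a proper name (no small RNA, pseudogene, antisense, clone, reading-frame or similar placeholder name), up to 4 members of each gene list, and the named genes on in 1 line and off in the other. The parts of that rule that need a p-value were dropped, and list members were taken by the size of their difference in place of the smallest adjusted p. Some list members that this rule takes are not reported here. In the same way 27 gene lists were fixed. They cover T cell receptor and surface identity, T cell receptor signalling, costimulation and the TNF superfamily, NF-kB, immediate early genes, cytokines and helper T cell factors, thymocyte and leukaemia transcription factors, adhesion and migration, the PTB family, hnRNP proteins, mRNA stability factors, SR proteins and the spliceosome, neuronal genes, glycolysis, cholesterol synthesis, proliferation, apoptosis, the stress response, interferon-stimulated genes, HLA and antigen presentation, 5 other cell types, and mitochondrially encoded and ribosomal protein genes as signs of RNA quality. The median difference of each of the 23 lists with at least 5 measured members was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins. This percentile describes these libraries.

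Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter, a mean FPKM of at least 5, quantile normalization, scaling to the median log ratio, and other limits for genes on or off. Others were chosen after the data were seen: a 4-fold rule, protein-coding genes only, at least 20 reads, a counting interval beyond 2-fold, scaling without mitochondrial genes, removal of the trend on GC content and gene length in 25 bins each, and subtraction of the median of the 25 nearest expressed genes. Reads were assigned without strand as far as the kit tells, so genes that overlap, and receptor or immunoglobulin segments with near-identical copies, carry an uncertain share of reads. Genes named below that overlap another expressed gene include CHUK, BAD, CTSW, SRRM2, PRPF6, RAVER2, HNRNPLL, HNRNPAB, PCBP1, IGF2BP1, CELF2, HK2, DHCR7, SREBF2, TOP2A, RAB3A, TAGLN, RPL4, MT-CO3 and MT-ATP8.

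The steps were tested on simulated data for D1.1 against B2.7 with shCtrl. Reads were drawn for 58676 genes, with 200 of the 12792 genes past the filter altered. They were drawn from the Poisson model that the intervals assume, with no variation between cultures or library preparations. The rates below therefore cover counting error alone. The rule of size recovered 98% of genes raised 4-fold, 78% of genes lowered 4-fold, 100% of genes raised 8-fold and 88% of genes lowered 8-fold, and it took 0.365% of unaltered genes. The ratio intervals held the true fold for 95.1% of genes, and 5.5% of unshifted random lists lay outside the central 95%. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.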

Results

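RNA-seq expression was compared between D1.1 and B2.7, subclones of the Jurkat human T cell line, both carrying a control hairpin. D1.1 is known for constant display of CD40 ligand, and B2.7 for its lack. The labels give 2 samples per group, and the deposited tables hold 1 value per gene and line. The B2.7 value rests on 26414843 reads in total and the D1.1 value on 22301660 reads. Of 58676 genes, 25189 had an FPKM above 0 in B2.7 and 24405 in D1.1. With 1 value per line, none of the differences below has a replicate check, and all intervals are counting error only.

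The series title sets D1.1 against B2.7. CD40LG, which encodes the CD40 ligand that T cells use to help B cells, stood at 48.3 FPKM (46.2 to 50.5) in D1.1 and at 0.354 FPKM (0.206 to 0.567; 17 reads) in B2.7. The ratio was 136 (84.9 to 234). The gene lies on chromosome X from 136648193 to 136660390. Activation genes such as CD69 and EGR1 and the lipid-presenting molecule CD1B were also higher in D1.1, whereas interferon-stimulated genes such as BST2, the integrin gene ITGAL and the telomerase gene TERT were lower.

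Among 12792 genes with a mean FPKM of at least 1, 385 (3.01%) were at least 2-fold higher in D1.1, 386 (3.02%) were at least 2-fold lower, and 12021 (94.0%) lay within 2-fold on the log2(FPKM + 1) scale. Of these, 252 of the higher and 177 of the lower genes were protein-coding. Fewer than 20 reads over both libraries stood behind 55 of the higher and 88 of the lower genes. Across genes, which are not independent replicates, Pearson's r between the lines was 0.946 and Spearman's rho 0.932. The median gene differed by -0.05 on the log2 scale.

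**Figure D1:**
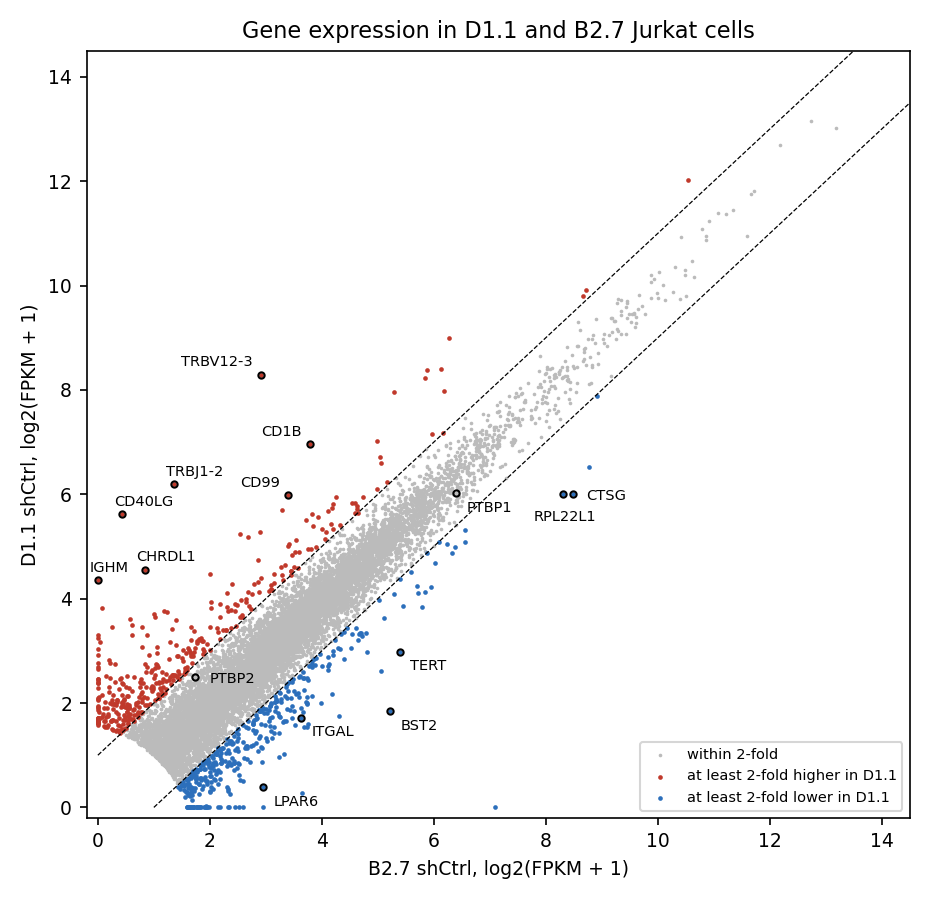
Each point is a gene with a mean FPKM of at least 1, with log2(FPKM + 1) in B2.7 on the horizontal axis and in D1.1 on the vertical axis, 1 value per line. Dashed lines mark a 2-fold difference, red points are the 385 genes at least 2-fold higher in D1.1, blue points the 386 at least 2-fold lower, and circles mark genes named in the text.

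Among genes with a proper name, the 10 with the largest log2(FPKM + 1) difference in the direction of D1.1 included CD40LG and segments of the T cell receptor beta chain. TRBV12-3 (chromosome 7, 142560423 to 142560931), the variable segment known from the Jurkat receptor, stood at 313 FPKM in D1.1 and 6.57 FPKM in B2.7, a ratio of 47.6 (37.7 to 61.2). TRBJ1-2, a joining segment whose position lies inside the annotated span of TRBC1, had 77 reads in D1.1 and 2 in B2.7. IGHM, the constant region of immunoglobulin mu (chromosome 14, 105854220 to 105856218), stood at 19.4 FPKM in D1.1 and had 0 reads in B2.7. Set against a floor of 3 reads it was 253-fold higher, with a counting interval from 206. ZNF738, a zinc finger gene, was likewise at 8.50 FPKM against 0 reads, 292-fold higher against that floor, with a counting interval from 237. CHRDL1, an antagonist of bone morphogenetic proteins, was 28.8-fold higher (23.1 to 36.5) and NUDT11 52.1-fold higher (29.6 to 102). CD1B reached 124 FPKM against 12.9 FPKM, a ratio of 9.61 (8.74 to 10.6). It lies in a stretch of chromosome 1 whose 25 expressed genes had a median of 0.32 above that of all genes. KDELC1 was 23.5-fold higher (16.3 to 35.1), and TUBAL3 had 320 reads in D1.1 and 1 in B2.7.

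In the other direction BST2, an interferon-stimulated protein that tethers virus particles to the cell surface, was 14.0-fold lower in D1.1 (10.9 to 18.2), at 2.60 FPKM against 36.4 FPKM. The gene lies on chromosome 19 from 17402939 to 17405648. LPAR6, a receptor for lysophosphatidic acid that sits within RB1 and can share its reads, was 21.8-fold lower (15.2 to 32.5). It lies in a chromosome 13 stretch with a median of -0.37 relative to all genes. TERT, the catalytic subunit of telomerase, stood at 6.93 FPKM against 41.0 FPKM, 5.91-fold lower (5.47 to 6.41). CTSG, the granule protease cathepsin G, was 5.66-fold lower (5.39 to 5.93), at 63.6 FPKM against 360 FPKM. RPL22L1, a paralog of a ribosomal protein, was 4.98-fold lower (4.80 to 5.17), BEX5 7.93-fold lower (6.01 to 10.6) and CLEC11A, a growth factor for blood cells, 6.24-fold lower (5.31 to 7.37). The immunoglobulin diversity segments IGHD1-7, IGHD1-1 and IGHD3-16 completed the 10 lowest among genes with a proper name, with 3, 2 and 4 reads in B2.7 and 0 in D1.1, too few for a statement.

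At an FPKM of at least 5 in 1 line and under 0.1 in the other, 10 genes were on in D1.1 and off in B2.7. The 6 with a gene name were IGHM, ZNF738, TUBAL3, RASL10B, ATF7IP2 and IGHD5-12. RASL10B, a small GTPase gene that overlaps TAF15, stood at 7.23 FPKM in D1.1 against 0 reads. ATF7IP2 stood at 6.53 FPKM against 1 read, in a chromosome 16 stretch with a median of -0.34. IGHD5-12 had 3 reads in D1.1 and 0 in B2.7. Of 3 genes on in B2.7 and off in D1.1, IGHD1-7 was the 1 with a gene name.

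PTBP1, the polypyrimidine tract-binding protein of most tissues and the gene that the shPTB name points to, was at 83.0 FPKM in B2.7 and 63.7 FPKM in D1.1 (chromosome 19, 797075 to 812327). The ratio of D1.1 to B2.7 was 0.768 (0.748 to 0.788). PTBP2, its neuronal paralog, stood at 2.34 FPKM in B2.7 and 4.67 FPKM in D1.1, a ratio of 2.0 (1.83 to 2.19). PTBP3 was near equal, at 23.4 FPKM and 25 FPKM, a ratio of 1.07 (1.03 to 1.11). None of the 9 measured members of the PTB family and partners passed the 2-fold rule. HNRNPLL, a splicing regulator of CD45 in lymphocytes, was 1.65-fold higher in D1.1 (1.52 to 1.79) in a chromosome 2 stretch with a median of 0.37, and RAVER2 1.32-fold higher (1.21 to 1.45). The family's median of 0.01 turned to -0.03 with a mean FPKM of at least 5.

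**Figure D2:**
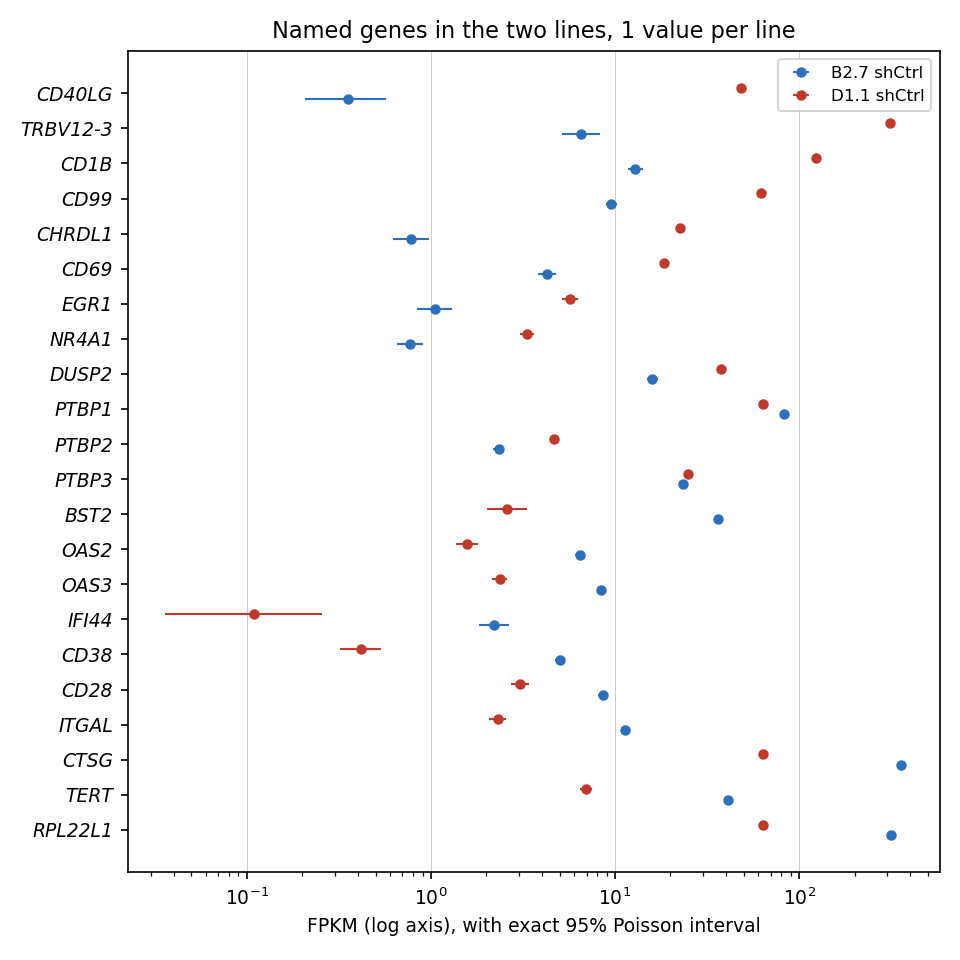
FPKM of 22 named genes on a log axis, blue for B2.7 and red for D1.1, with 1 value per line and exact 95% Poisson intervals as bars. CD40LG, TRBV12-3 and CD1B sit far to the right in D1.1, and BST2, IFI44 and CD38 far to the left.

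T cell identity genes went both ways. Of 24 measured genes for the T cell receptor complex and T cell surface, 3 were at least 2-fold higher in D1.1, 5 were lower and 16 lay within 2-fold. CD1E, another lipid-presenting molecule of cortical thymocytes, was 4.61-fold higher (3.78 to 5.65), in the same chromosome 1 stretch as CD1B. CD38, an ectoenzyme of activated lymphocytes, was 12-fold lower (9.30 to 15.7), CD96 4.98-fold lower (4.25 to 5.85) and the costimulatory receptor CD28 2.81-fold lower (2.49 to 3.19). The median was -0.05, at percentile 48.0 of random lists. It was 0.01 with median scaling and 0.11 with a mean FPKM of at least 5, and -0.15 at percentile 1.68, outside the central 95%, with the median of the 25 nearest expressed genes subtracted. The bootstrap range over members of that last median spans 0 (-0.75 to 0.21). Of 33 signalling genes downstream of the receptor, 1 was higher, the adaptor SH2D2A at 2.59-fold (2.09 to 3.22) in that same stretch, and 1 was lower, the CSK-binding adaptor PAG1 at 3.25-fold (2.88 to 3.66). The kinase ZAP70 was 1.73-fold higher (1.68 to 1.78) and PRKCQ 1.79-fold lower (1.60 to 1.99). The median of this list was -0.06, at percentile 46.5, and 0.0038 with median scaling.

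Immediate early and activation genes, which T cells induce on receptor stimulation, stood together above B2.7. Of 20 measured, 19 were above 0 and 4 were at least 2-fold higher, with none at least 2-fold lower. CD69 was 4.31-fold higher (3.81 to 4.89), EGR1 5.45-fold (4.31 to 6.95), NR4A1 4.31-fold (3.59 to 5.20) and the phosphatase DUSP2 2.37-fold (2.18 to 2.58). The list median of 0.58 lay above all 10000 random lists. With 1 value per line, culture or handling on the day of harvest cannot be told apart from a lasting difference between the subclones. The same holds for a difference in how the lines carry the hairpin, since no sample lacks one. Of 17 costimulatory and TNF superfamily genes, 3 were higher and 1, CD28, was lower. Beside CD40LG, TNFRSF25 was 6.48-fold higher (5.15 to 8.24), although it overlaps PLEKHG5 and ESPN, and the inhibitory receptor PDCD1 had 110 reads against 3. The median of 0.21 was at percentile 98.9, with a bootstrap range over members of -0.39 to 0.90. It turned to -0.13 with a mean FPKM of at least 5 and, with the nearest genes subtracted, lay on the border of the central 95% (percentiles 97.4 to 98.0 over 10 further draws of random lists). Of 23 NF-kB genes, 2 were higher, the adhesion molecule ICAM1 at 7.13-fold (5.29 to 9.79) and TNFAIP2 at 4.08-fold (3.59 to 4.65), the latter in a chromosome 14 stretch with a median of 0.45. CD83 was 1.5-fold higher (1.37 to 1.64), CHUK was 1.45-fold higher (1.36 to 1.55), and the list median of 0.04 was at percentile 87.5.

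Among 17 cytokine, cytokine receptor and helper T cell genes, 3 were at least 2-fold higher on the log2(FPKM + 1) scale and none at least 2-fold lower. The higher ones included the transcription factors MAF and EOMES. MAF was 13.2-fold higher (9.45 to 18.9) and EOMES 4.77-fold (3.29 to 7.08), from 0.206 and 0.373 FPKM in B2.7. The receptor gene IL9R was at 1.49 FPKM against 3.76 FPKM, within 2-fold on the log2(FPKM + 1) scale. The median was 0.28, at percentile 99.5, with a bootstrap range over members that spans 0 (-0.15 to 0.53). Of 33 thymocyte and leukaemia transcription factors and partners, 2 were higher and 1 was lower. DNTT, the terminal transferase of immature lymphocytes, was 13.9-fold higher (8.49 to 24.4). TOX2 was 5.50-fold higher (3.78 to 8.23), in a chromosome 20 stretch with a median of 0.32, and TCF7, a transcription factor of T cell development whose gene overlaps SKP1, was 2.33-fold lower (2.27 to 2.39). NKX2-1 was at 2.92 FPKM against 1.08 FPKM, within 2-fold on the log2(FPKM + 1) scale, in a chromosome 14 stretch with a median of 0.33. The median was 0.15, at percentile 99.3, again with a bootstrap range that spans 0 (-0.01 to 0.32). With the nearest genes subtracted, the cytokine list was at percentile 97.4 and the transcription factor list at 90.4, both inside the central 95%.

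Adhesion and migration genes leaned lower. Of 32 measured, 8 were at least 2-fold lower in D1.1 and 5 were higher. The median of -0.38 lay below all 10000 random lists, although its bootstrap range over members reached 0.06 (-0.68 to 0.06), and it was -0.25 at percentile 0.04 after removal of the GC and length trend. ITGAL, the alpha chain of the leukocyte integrin LFA-1, was 4.95-fold lower (4.41 to 5.58), in a chromosome 16 stretch with a median of -0.35, and the chemokine receptor CXCR3 6.15-fold lower (4.24 to 9.20). CD99, a surface glycoprotein of leukocytes, was 6.55-fold higher (6.08 to 7.06), and the chemokine receptor CCR8 17.3-fold higher (8.08 to 44.0).

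Interferon-stimulated genes were lower in D1.1 as a group. Of 33 measured, 30 were below 0 and 7 were at least 2-fold lower, with none at least 2-fold higher. Beside BST2, the antiviral synthetases OAS2 and OAS3 were 4.09-fold lower (3.54 to 4.76) and 3.55-fold lower (3.20 to 3.95), and IFI44 was 20.1-fold lower (8.37 to 63.0) on 5 reads in D1.1. The list median of -0.57 lay below all 10000 random lists. Of 17 HLA and antigen presentation genes, HLA-B was 3.77-fold higher (3.17 to 4.50), a value that reads of other class I genes can affect, and the peptide-trimming protease ERAP1, which overlaps CAST, was 2.80-fold lower (2.57 to 3.07). The peptide-loading factor TAPBP was 1.77-fold lower (1.65 to 1.89) and the class I transactivator NLRC5 2.04-fold lower (1.80 to 2.31). The median was -0.26, with a bootstrap range that spans 0 (-0.58 to 0.10), at percentile 1.61, which moved to 3.31 after removal of the GC and length trend and to 2.53 with the nearest genes subtracted, just inside the central 95%.

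Cholesterol synthesis genes were mostly higher by a small amount. Of 22 measured, 17 were above 0 and all lay within 2-fold, with a median of 0.28 at percentile 99.96. IDI1 was 1.73-fold higher (1.66 to 1.81), INSIG1, a sterol-regulated gene, 1.60-fold (1.54 to 1.65) and DHCR7 1.43-fold (1.35 to 1.52), while SREBF2, which encodes a regulator of the pathway, was 1.39-fold lower (1.33 to 1.45) in a chromosome 22 stretch with a median of -0.35. All 23 glycolysis genes lay within 2-fold. Their median was 0.10, at percentile 92.9, with PGK1 1.51-fold higher (1.48 to 1.54), PFKP 1.40-fold higher (1.33 to 1.48), SLC2A3 1.64-fold higher (1.36 to 1.99) and HK2 1.53-fold lower (1.42 to 1.65).

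In the 3 lists of RNA-binding proteins beside the PTB family, all measured members lay within 2-fold. These were 23 hnRNP genes (median -0.10, percentile 13), 34 mRNA stability factors (median 0.02, percentile 77.1) and 47 SR protein and spliceosome genes (median -0.04, percentile 42.2, and 0.02 with median scaling). HNRNPD was 1.58-fold lower in D1.1 (1.53 to 1.63) and PCBP1 1.52-fold lower (1.39 to 1.66). HNRNPAB was 1.47-fold lower (1.42 to 1.53), in a chromosome 5 stretch with a median of -0.30. UPF3A, of nonsense-mediated decay, was 1.78-fold lower (1.67 to 1.90), while ZFP36, which destabilises AU-rich transcripts, was 1.69-fold higher (1.49 to 1.93) and IGF2BP1 1.44-fold higher (1.37 to 1.53). CELF2 was 1.88-fold higher (1.79 to 1.98), QKI 1.75-fold higher (1.63 to 1.88) and PRPF6 1.62-fold higher (1.53 to 1.72), against SRRM2 at 1.76-fold lower (1.72 to 1.80), in a chromosome 16 stretch with a median of -0.37.

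Of 12 neuronal genes, 2 were higher: INA, a neurofilament protein, with 241 reads against 1, and the motor protein KIF5A at 5.35-fold (3.97 to 7.33). RAB3A was 1.85-fold lower (1.38 to 2.51). The median was 0.16, at percentile 93.9. Of 40 proliferation genes, CCND2, a D-type cyclin, was 4.67-fold higher (4.12 to 5.31) and the cell cycle inhibitor CDKN1A 7.6-fold higher (5.33 to 11.1), and the other 38 lay within 2-fold. TOP2A was 1.83-fold higher (1.78 to 1.89) and AURKA 1.73-fold higher (1.64 to 1.83). The median of that list was -0.08, at percentile 16.6, and its mean was 0.06. All 27 apoptosis genes lay within 2-fold on the log2(FPKM + 1) scale. Their median was -0.05 at percentile 50.4 and 0.0044 with median scaling, and their mean was 0.01. Among them BAD was at 1.31 FPKM against 2.59 FPKM, CFLAR at 0.924 FPKM against 1.98 FPKM, PMAIP1 was 1.55-fold higher (1.46 to 1.65) and CYCS 1.46-fold higher (1.43 to 1.49). Of 33 stress response genes, DDIT4 was 3.09-fold higher (2.54 to 3.77) and ATF3 2.77-fold higher (2.32 to 3.31), and 3 were lower, among them CHAC1 at 2.85-fold (2.43 to 3.35) and STC2 at 2.66-fold (2.38 to 2.98). Their median was -0.17, at percentile 3.44.

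**Figure D3:**
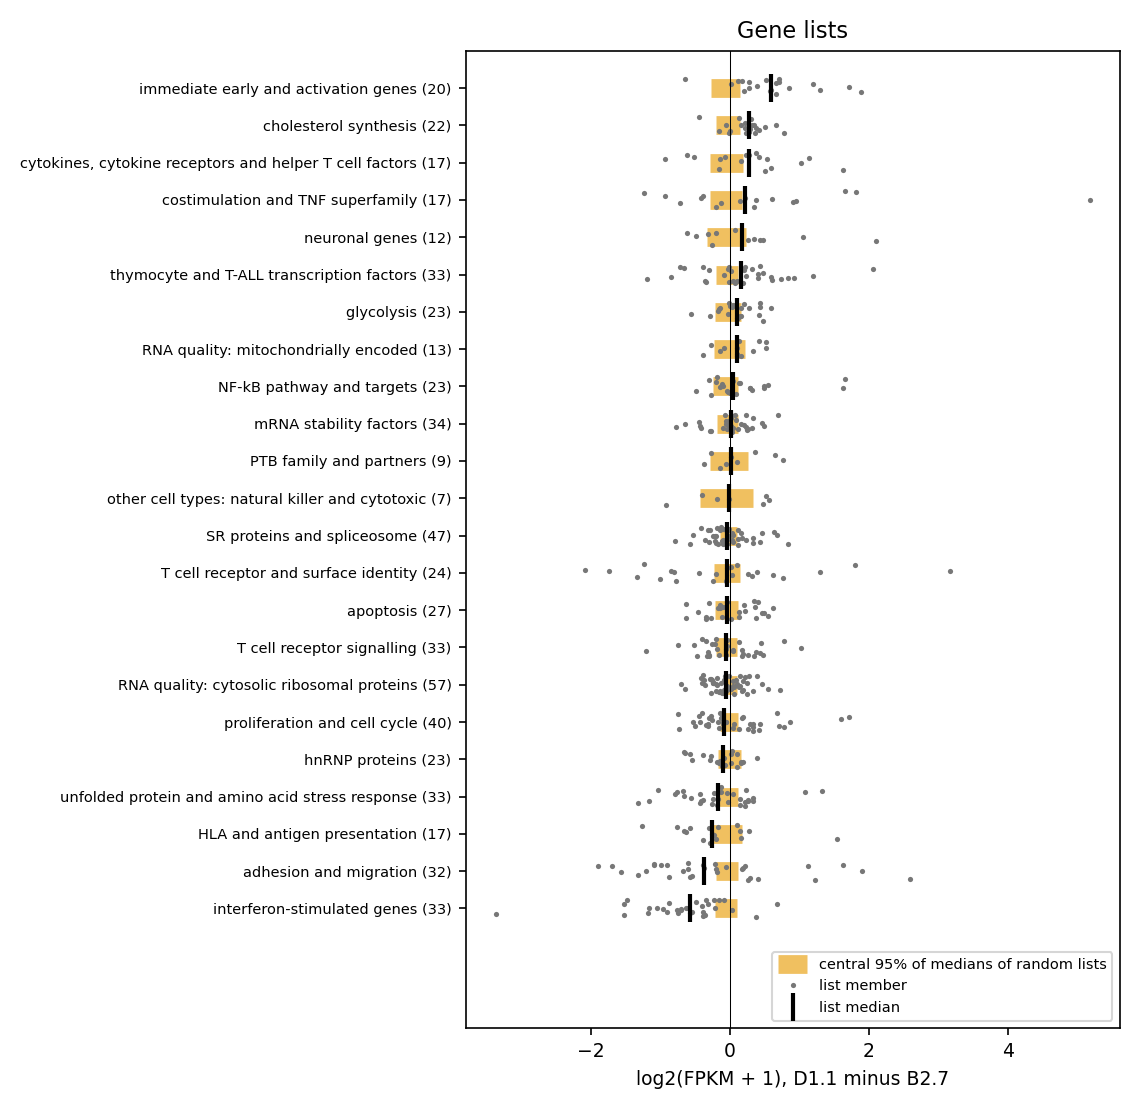
Differences in log2(FPKM + 1), D1.1 minus B2.7, for the 23 gene lists with at least 5 measured members, whose number stands in brackets. Grey points are genes, black bars list medians and yellow bars the central 95% of medians of 10000 expression-matched random lists; the immediate early genes lie farthest to the right at 0.58 and the interferon-stimulated genes farthest to the left at -0.57.

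In all, 8 of the 23 lists lay outside the central 95% of random lists. With the nearest genes subtracted the number was 5, and 5 to 6 in 10 further draws. That step left out the mitochondrially encoded list and drew its random lists from protein-coding genes alone, so the 2 numbers are not fully alike. Random lists leave out that neighbouring genes can differ together, so the number has no stated chance level. Among markers of other cell types, 4 of 22 myeloid genes were measured, and CTSG, S100A9 and CEBPE were lower in D1.1 while AIF1 was 1.29-fold higher (1.23 to 1.34). CEBPE was 4.26-fold lower (3.31 to 5.53), and S100A9 had 3 reads in D1.1 against 46. These 4 genes are too few for placement among random lists, and no link to the interferon-stimulated or adhesion genes was tested. Of 16 B cell markers, 2 were measured, and IGLL1 was 3.52-fold higher in D1.1 (3.34 to 3.72) and CD79A 2.15-fold higher by FPKM (1.80 to 2.57), the latter within 2-fold on the log2(FPKM + 1) scale. The 7 natural killer and cytotoxic genes lay within 2-fold on that scale. Their median of -0.02 at percentile 59.8 turned to 0.02 with median scaling. Of these NKG7 was at 3.31 FPKM against 7.17 FPKM, GZMH at 3.39 FPKM against 1.99 FPKM, GZMB at 1.65 FPKM against 0.859 FPKM and CTSW at 8.79 FPKM against 6.03 FPKM. The erythroid or megakaryocyte genes measured were EPOR and GP1BA, and those of epithelium or fibroblasts COL6A2, THY1, SPARC and TAGLN, all within 2-fold on the log2(FPKM + 1) scale.

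As signs of RNA quality, mitochondrially encoded transcripts took 4.35% of reads in B2.7 and 5.04% in D1.1. The 13 measured protein-coding ones lay within 2-fold, with a median of 0.10 at percentile 81.4 that turned to -0.04 with quantile normalization. Of these MT-ND3 was 1.44-fold higher (1.40 to 1.47), MT-CO3 1.43-fold (1.42 to 1.44) and MT-CO2 1.33-fold (1.32 to 1.34), and MT-ATP8 had 17 reads against 28. With quantile normalization the log2 difference of MT-CO3 went from 0.52 to 0. Of the mitochondrial ribosomal RNAs, which are not in that list and were named after their values were seen, the large MT-RNR2 was past the 2-fold rule at 2.81-fold higher in D1.1 (2.78 to 2.83), while the small MT-RNR1 had a ratio of 0.884 (0.870 to 0.898). All 57 ribosomal protein genes also lay within 2-fold, with a median of -0.07 at percentile 8.44. RPL4, in a chromosome 15 stretch with a median of 0.58, was 1.65-fold higher (1.63 to 1.67) and RPLP1 1.46-fold higher (1.44 to 1.48), whereas RPL21 was 1.63-fold lower (1.62 to 1.65) and RPL35 1.57-fold lower (1.55 to 1.60). The 10 most abundant genes took 5.96% of reads in B2.7 and 6.48% in D1.1.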

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

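The 4-fold rule, the limits to protein-coding genes and to at least 20 reads, the count by intervals beyond 2-fold, scaling without mitochondrial genes, the GC and length correction and the subtraction of neighbouring genes were chosen after the data were seen. No paired analysis was possible because the tables hold 1 column per line, without replicate letters. For the same reason limma with its trend, robust and smaller-fit forms, the replicate block, leaving out each library, camera, fry, the shPTB and interaction contrasts and the overlap of calls were not run. The counts of 385 higher and 386 lower genes depended on how low values were treated: 596 and 725 with a pseudocount of 0.1, 92 and 58 with a pseudocount of 5, 132 and 125 with a mean FPKM of at least 5, 63 and 29 with a 4-fold rule, and 252 and 177 among protein-coding genes. The last 3 count fewer genes by construction. Counts stayed within 1.5 times under quantile normalization (417 and 342), median scaling (422 and 346), without mitochondrial genes (400 and 388), with no filter (512 and 516), with at least 20 reads (330 and 298) and with intervals beyond 2-fold (361 and 278). The interval count uses the FPKM ratio without a pseudocount, so its genes are not a subset of the 385 and 386. NKX2-1, with an interval from 2.11 and a log2 difference of 0.92, is in the interval count only. Genes on in D1.1 or in B2.7 alone numbered 10 and 3, but 172 and 148 with an on limit of 1 and 16 and 6 with an off limit of 0.5. The log2 difference of CD40LG was 6.73 with a pseudocount of 0.1 and 3.31 with one of 5, that of PTBP2 0.97 and 0.40, and that of PTBP1 -0.32 with median scaling; all kept their direction, and the moves with the pseudocount follow from its construction. Among 766 alternatives for 116 other named genes, 624 stayed within the counting interval, 142 moved beyond it and 0 of the genes past 2-fold changed sign. The filter settings leave a gene's own value unaltered, so those entries stayed by construction. A pseudocount shared by both lines cannot change a sign, so the 0 was settled in advance for those settings too. Of 204 for the 23 lists, 197 stayed within the bootstrap range, 6 moved and 1 reversed. The setting with no filter cannot move a list median, since the members had already passed the filter. The reversed list was costimulation, -0.13 with a mean FPKM of at least 5, which leaves fewer genes. That value lies within the list's bootstrap range of -0.39 to 0.90, and the cause was not tested further. Reversal was counted only for lists outside the central range of random lists; in all 16 of the 204 changed the sign of a median, in 10 lists, and the others were of lists inside that range. Lists outside it numbered 8, 7 after the GC and length correction, which lost HLA, and 5 with neighbours subtracted, which brought in T cell identity and lost HLA, cytokines and transcription factors, inside the range in all 10 further draws of random lists too. Costimulation was on the border and outside in 8 of those 10, so the number was 5 to 6. The subtraction left out the mitochondrially encoded list and drew its random lists from protein-coding genes alone. Depth limits genes near the floor of 3 reads, such as the immunoglobulin diversity segments named above, which are short.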

Other observations

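The tests of a mixed library, of shared receptor reads and of the day of harvest were chosen after the values were seen, as were the genes named only here; the other tests below were set down before their results. Genes of the T cell receptor beta chain beyond the rule for named genes differed by segment. TRBC1, the constant gene downstream of the TRBJ1 segments, stood at 508 FPKM in D1.1 and 76.5 FPKM in B2.7, a ratio of 6.64 (6.36 to 6.94), although its annotated span takes in several other segments. TRBC2 was at 79.8 FPKM in D1.1 and 81.1 FPKM in B2.7, a D1.1 to B2.7 ratio of 0.984 (0.915 to 1.06). On the alpha chain TRAC was 3.28-fold higher in D1.1 (2.86 to 3.77) and TRAV8-4 3.08-fold higher (2.61 to 3.64). Others went the other way: the beta joining segment TRBJ2-7 was 4.04-fold lower in D1.1 (2.25 to 7.78), and on the gamma chain TRGC2 was 1.95-fold lower (1.55 to 2.46) and the pseudogene TRGV7 3.08-fold lower (2.01 to 4.85). The partner chains of the receptor were near equal, with ratios of 1.08 for CD3D, 1.24 for CD3E, 0.971 for CD3G and 0.961 for CD247. Outside the receptor, the long noncoding gene CH507-513H4.6 on chromosome 21 had 3289 reads in B2.7 and 0 in D1.1. Whether near-identical copies share its reads was not examined, so this split is not read as a difference in expression.

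The receptor beta difference was weighed against reads shared between TRBC1 and TRBC2, which are near-identical. Reads moved between them leave their sum unaltered. The summed reads, 14580 in D1.1 and 3983 in B2.7, differed 4.34-fold (4.19 to 4.49) when scaled to library totals. Reads moved between the 2 genes therefore do not account for the whole difference. Shared reads that a counter drops would alter the sum, and the counter is not given, so that form of sharing was not tested. The TRBV12-3 level left in B2.7, 2.10% of that in D1.1, was weighed against RNA of D1.1 mixed into the B2.7 library. A mixture at even the lower bound of 1.64% would bring reads of every D1.1 gene. Yet 2 genes, ZNF738 and ATF7IP2, had fewer reads in B2.7 than that after Bonferroni adjustment over 6644 genes (0 against 14.4 and 1 against 18.1). That is the least number the rule asked for, and both genes were already known as off in B2.7. CD40LG stood at 0.734% but did not pass that adjustment. The source of the level left in B2.7 stays open, and no biological explanation of it was tested.

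The lower interferon-stimulated genes in D1.1 were not removed by any correction run. After removal of the trend on GC content and gene length the list median was -0.59, below the central range of random lists (-0.16 to 0.15). After subtraction of the 25 nearest expressed genes it was -0.53, again below that range (-0.13 to 0.12), so neither a GC or length trend nor shifts of chromosome regions account for the whole of it. A difference in culture or handling on the day of harvest cannot be told apart from a lasting difference between the subclones, because the tables hold 1 column per line. No sample of either line lacks a hairpin, so a difference in how the lines carry it cannot be told apart either. A lower interferon tone in D1.1 is therefore a hypothesis and may belong to the day or the hairpin as much as to the line.

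Neighbouring genes differed together along the chromosomes. Of 398 windows of 25 expressed protein-coding genes, 44 had a median at least 0.3 away from that of all genes, 20 higher and 24 lower in D1.1, against at most 3 in 1000 shuffles of gene positions. The count was 27 after removal of the GC and length trend (shuffled maximum 3) and 26 of 249 windows without overlapping genes and tandem paralogs (shuffled maximum 3), so chance order, a GC or length trend, and shared reads do not account for the whole of it. On chromosome 15 the 4 windows from 45361124 to 68198603 had medians of 0.42 to 0.58, with 97 of 100 genes above the median of all genes, while the window from 34224999 to 40755851 had a median of -0.34 and the whole chromosome one of -0.01; chromosome 22 as a whole had a median of -0.35 and chromosome 14 one of 0.29 relative to all genes. These medians, and those of the stretches given beside named genes above, are without removal of the GC and length trend. Across genes Spearman's rho of the difference with GC content was -0.19, so that trend can hold part of any single median. Which of the stretches pass 0.3 after its removal is not reported here. Differences in copy number between the subclones are a candidate explanation that these data may reflect, untested without DNA, and they would also touch named genes in such stretches, such as RPL4, ITGAL and SREBF2.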
